A study of Mus musculus with 14 samples.

How the data were processed

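RNA was measured in 14 mouse libraries, 2 in each of 7 groups (ESC, EpiSC, MM401 day 3, MM401 P2, rES passage 6, rES passage 30 and rES passage 30 without MM401), and the series design text calls the 2 libraries of a group biological duplicates. The title of MM401 P2 replicate 2 reads P2b where that of replicate 1 reads P2, and whether both came from the same culture or passage is not given in the sources used here. Per the labels' protocols, RNA was purified with RNeasy columns and DNase and sequenced single-end from Illumina TruSeq libraries. The authors deposited a table of raw read counts for 24015 gene symbols, and these counts are the only values used. The submitters' processing notes name TopHat2, Subread, DESeq and the build mm9, with no versions, roles or order. The strand of the libraries and the rule for reads that map to several places are not given in the sources used here. A further 2 columns match no sample label and were not used, and 27 names had been read as dates (at most 0.254% of the counts of a library).

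Libraries held 20831588 to 23677089 counts, except for MM401 day 3 (113221270 and 116086115) and MM401 P2 (74952496 and 80383376). Between 17972 and 19185 genes had a count. The ribosomal RNA precursor Rn45s held 0.35% to 2.005% of counts, the highest in rES passage 30 replicate 2. It held 1.391% to 1.9% in the MM401 day 3 and P2 libraries, against 0.435% and 0.35% in EpiSC and 0.592% and 0.598% in ESC. Log2 counts of replicates had a Pearson r between 0.9973 and 0.9987. Their scatter over counting error (chi-square per degree of freedom) ran from 1.28 in ESC to 8.77 in MM401 P2, where depth is high. Depth alone does not order these values, as the scatter was 6.89 in the still deeper MM401 day 3 libraries. It was 4.55 in rES passage 30 and 3.22 without MM401, at depths near that of ESC. The tests share 1 trend of spread over all groups. Chromosome names and gene order came from tables of a later assembly than mm9 by symbol (23836 symbols matched, 99.3%), and transcript length and GC content from GENCODE M21 transcripts, so coordinates are not given.

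Genes were kept with filterByExpr (16247 genes), scaled with TMM, and tested in R 4.3.3 with the robust quasi-likelihood F test of edgeR 4.0.16 on all 14 libraries with 1 mean per group. A gene was called at an adjusted p (Benjamini-Hochberg, within each comparison) under 0.05, two-sided, and every adjusted p of a gene is from this test. Rose, fell, higher and lower refer to called genes. The standard error of a log2 fold change is its absolute value divided by the square root of F. Such p-values measure only the spread between these libraries. The comparisons were ESC, MM401 day 3, MM401 P2 and rES passage 30 against EpiSC, rES passage 30 against ESC, rES passage 30 without MM401 against with it, and 5 secondary comparisons (MM401 P2 against day 3, rES passage 6 against EpiSC and ESC, rES without MM401 against ESC, and rES passage 30 against passage 6). Groups, comparisons, tests and most alternatives were chosen before the data were examined.

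A set of 28 gene lists from general knowledge, and all X-linked genes, was tested with camera in limma 3.58.1 at its preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Where the call was lost with the estimated correlation, that p is given. Named genes are a fixed panel of 17, the largest called rises and falls of a comparison among genes of at least 10 CPM in either group (up to 10 of each, or 4 in secondary comparisons) and up to 4 called members of a list by smallest adjusted p, and any other gene is marked as chosen after its value was seen. Position between EpiSC and ESC is a least-squares slope of log2 CPM (counts scaled to library size) (prior count 2) on the ESC minus EpiSC difference.

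The pipeline was tested on simulated data whose spread followed the 1 trend fitted over all groups. Differences in spread between genes of like level or between groups were not simulated, so the rates below may differ from those in these data. In simulated MM401 day 3 against EpiSC, 84% of 50 genes changed 2-fold and 62% of those changed 1.25-fold were called, and 8.42% of calls were false. In simulated rES passage 30 against EpiSC, 36% of the genes changed 1.25-fold were called. A group simulated halfway between EpiSC and ESC was placed at 0.495. Alternatives were RLE size factors, total counts, no filter, the Wald test of DESeq2 1.42.0, a fit of the 4 libraries compared, a 2-fold threshold, a replicate block, each library left out, and for positions all genes or a prior count of 0.5. Chosen after the data were seen were thinning to the shallowest library, leaving out Rn45s, leaving out genes that follow the feeder markers, and fits without the deeper MM401 libraries or rES passage 30 replicate 2.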

Results

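RNA-seq counts were compared between 7 groups of mouse pluripotent cells with 2 libraries each. Embryonic stem cells (ESC), grown with LIF on feeder cells, stand for the naive state, and epiblast stem cells (EpiSC), grown with FGF, for the primed state. EpiSC were moved to LIF medium with 100 µM MM401, an inhibitor of the histone methyltransferase Mll1 (gene Kmt2a), for 3 days (MM401 day 3) or 6 days (MM401 P2, passage 2). Reverted lines (rES), kept at 25 µM MM401 after passage 3, were sampled at passage 6 and passage 30, and at passage 30 also after growth without MM401. LIF medium and MM401 were introduced together, so every comparison of treated cells with EpiSC covers both. The day 3 and P2 libraries were also deeper than those of EpiSC and ESC and held a larger share of Rn45s. Any technical difference behind this was not separable from treatment. The rES lines also carry a genotype label of their own (CD1-deltaTSIX/JF1, against CD1/JF1 in the other groups), so a comparison of rES with ESC or EpiSC holds the line as well as the state. Below, ± after a log2 fold change is its standard error, and CPM are group means of 2 libraries.

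**Figure D1:**
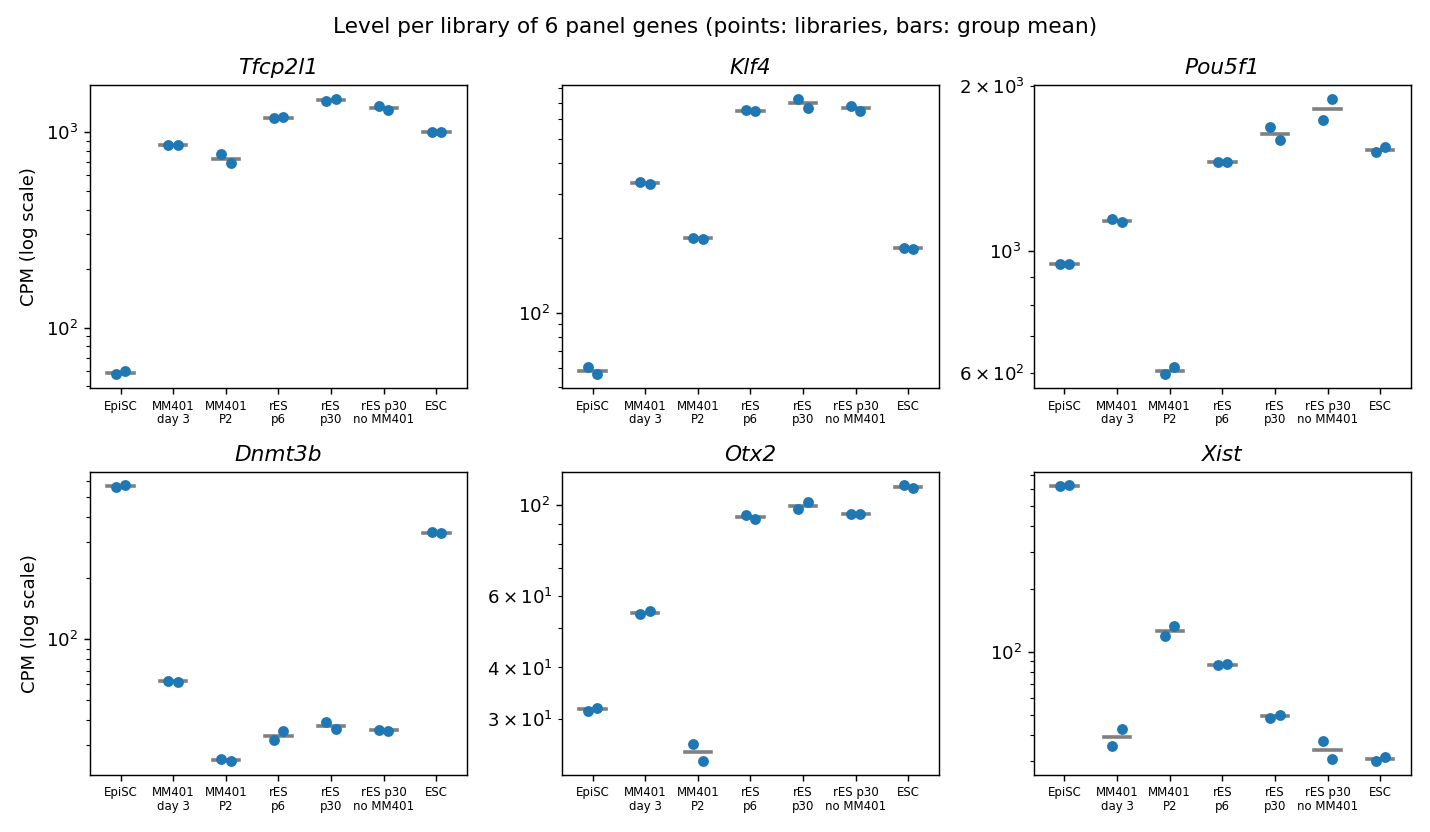
CPM on a log axis for 6 genes in each library, by group. The 2 libraries of a group lie close together for each gene, and Dnmt3b is lower in each treated and rES library than in EpiSC (mean 566.8 CPM).

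ESC and EpiSC differed at the genes that mark the naive and the primed state. All 22 measured genes of a naive pluripotency list rose in ESC, 22 also when adjusted over the list alone, with a median log2 fold change of 2.46 (camera adjusted p = 5.99e-57). Tfcp2l1 (4.09 ± 0.04, 17.0-fold), Zfp42 (3.83 ± 0.05) and Nr0b1 (3.66 ± 0.05) were among them, and Klf4 rose from 58.4 to 181 CPM. The general pluripotency factors Pou5f1 (0.69 ± 0.04, 950.1 to 1534 CPM), Sox2 (1.16 ± 0.04) and Nanog (0.50 ± 0.04) rose as well. In the primed pluripotency list 14 of 21 genes fell, 6 rose and Lef1, chosen after its value was seen, was not called (camera adjusted p = 9.88e-05, direction down, adjusted p = 0.0519 with an estimated correlation). Sox11 (-2.46 ± 0.07), Fzd2 (-2.33 ± 0.06) and Grb10 (-1.99 ± 0.04) fell, whereas Fgf5 (1.47 ± 0.16, 7.61 to 21.1 CPM) and Otx2 (1.81 ± 0.06, 31.6 to 110.8 CPM), listed as primed markers, were higher in ESC. Dnmt3b fell by 0.76 ± 0.04 in ESC, while Dnmt3l, its cofactor, rose by 6.26 ± 0.05.

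Primitive endoderm genes were also higher in ESC. All 14 measured rose in ESC, with a median of 3.81, or 3.76 with a gene at 0 counts in EpiSC set at its bound (camera adjusted p = 4.44e-22). Lama1 (5.87 ± 0.05), Gata4 (7.05 ± 0.19) and Col4a1 (2.81 ± 0.04) were among them. Genes of the integrated stress and unfolded protein response rose (16 of 18, median 1.48, camera adjusted p = 2.97e-13), with Cth (3.11 ± 0.05), Trib3 (2.66 ± 0.06) and Atf4 (1.55 ± 0.04), while the chaperones Hspa5 (-0.18 ± 0.04) and Hsp90b1 (-0.85 ± 0.04), chosen after their values were seen, fell. Of 21 glycolysis genes 20 rose (median 0.90, camera adjusted p = 1.12e-13), led by Pfkp (3.12 ± 0.04). Cholesterol synthesis genes fell (19 of 21, median -0.84, camera adjusted p = 1.41e-08), with Dhcr7 (-2.49 ± 0.05), and so did 19 of 23 cell cycle genes (median -0.45, camera adjusted p = 4.16e-05), with Top2a (-1.28 ± 0.03). Nodal and activin targets split, with 7 higher and 7 lower. Their median was 0.01 and their test pointed down (camera adjusted p = 0.0438, adjusted p = 0.128 with an estimated correlation, 0.0763 without ESC replicate 1 and 0.0663 without ESC replicate 2). Lefty1 (-2.99 ± 0.04) fell and Fst (3.11 ± 0.07) rose. Among genes of at least 10 CPM in either group, the limit used for all largest changes named here, the largest rises included Aqp8 (at least 690-fold), Gkn2 (at least 241-fold) and Hkdc1 (ratio 998, counting interval 179 to 39500), and the largest falls included Htr7 (-7.04 ± 0.21), Fosb (-5.70 ± 0.12) and the glucose-responsive gene Txnip (-5.58 ± 0.06). Folds against a group at 0 counts use a floor of 3 counts over the group, and such floors and intervals cover counting error only. In all, 12103 of 16247 genes were called, 6015 higher and 6088 lower in ESC, of which 2331 and 2192 changed at least 2-fold.

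After 3 days in MM401 and LIF most naive genes were well above their EpiSC level and the primed genes had fallen. Of 22 naive genes 21 rose against EpiSC (median 2.78, camera adjusted p = 1.22e-67) and Dppa3 was not called (0.19 ± 0.12, adjusted p = 0.148). Tcl1 (4.53 ± 0.06), Tbx3 (4.54 ± 0.06, 19.3 to 449.8 CPM), Zfp42 (4.14 ± 0.05) and Tfcp2l1 (3.87 ± 0.04) rose by over 10-fold, and Nanog by 1.76 ± 0.04 to 964.9 CPM against 402.5 CPM in ESC. Primed genes fell in 18 of 21 cases (median -2.48, camera adjusted p = 3.93e-20), among them Sox11 (-4.26 ± 0.07), Dnmt3b (-3.19 ± 0.04, 566.8 to 61.9 CPM), Fgf5 (-4.03 ± 0.21) and Grb10 (-2.77 ± 0.04). The 3 that rose were Otx2 (0.79 ± 0.05), Etv4 (1.98 ± 0.04) and Zic2 (0.32 ± 0.05), the last chosen after its value was seen. Nodal and activin targets fell in 12 of 15 cases (median -1.09, camera adjusted p = 3.8e-07), with Lefty1 at -4.59 ± 0.05, while the feedback inhibitor Smad7 rose by 1.65 ± 0.04.

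Other groups of genes moved apart at day 3. Germ line genes rose in 11 of 15 cases (median 0.95, camera adjusted p = 0.000955), with Dazl (3.63 ± 0.08) and Ddx4 (3.62 ± 0.13). LIF and STAT3 pathway genes rose in 12 of 15 cases (median 0.91, camera adjusted p = 1.05e-09), but Stat3 itself (-0.42 ± 0.04), Socs3 (-0.62 ± 0.04) and Junb (-0.33 ± 0.08), chosen after their values were seen, fell. Klf4, Tfcp2l1 and Gbx2 of this list are also on the naive list. Primitive endoderm genes rose in 11 of 14 cases, with a median of 1.37, or 0.66 with a gene at 0 counts set at its bound (camera adjusted p = 0.0051, adjusted p = 0.127 with an estimated correlation). Epithelial genes fell in 9 of 14 cases (median -1.37, camera adjusted p = 0.000479, adjusted p = 0.101 with an estimated correlation), with Cldn6 (-3.54 ± 0.08), Esrp1 (-3.61 ± 0.09) and Epcam (-1.58 ± 0.04), and Cdh1, chosen after its value was seen, was not called (-0.05 ± 0.04). Xist fell from 622 to 39.1 CPM (-3.99 ± 0.09), a value that may include antisense Tsix reads because the strand of the libraries is not given. The histone methyltransferase gene Kmt2a fell by 0.52 ± 0.04 and its partner Wdr5 rose by 1.45 ± 0.03. Crygc (7.01 ± 0.20), Vax2 (5.93 ± 0.16) and Krt42 (5.57 ± 0.11) were among the largest rises at this limit, and Vrtn (-7.19 ± 0.14) and Htr7 (-8.62 ± 0.19) were among the largest falls. Of 12443 genes called, 6292 were higher and 6151 lower, and 1906 and 2544 changed at least 2-fold. With RLE size factors 6163 were higher and 6268 lower. With scaling to total counts 38.6% of the called genes were higher in place of 50.6%, and the median of all genes moved from 0.00 to -0.17, with similar shifts in ESC (to -0.15) and rES passage 30 (-0.02 to -0.17).

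At P2 the naive genes stayed above EpiSC, and Hox, interferon and feeder-type genes were high. Of 22 naive genes 20 rose (median 2.21, camera adjusted p = 3.24e-41), with Tcl1 (4.29 ± 0.06), Tfcp2l1 (3.64 ± 0.04) and Zfp42 (3.44 ± 0.05). Gbx2 fell (-0.37 ± 0.07, chosen after its value was seen) and Dppa3 was not called (0.07 ± 0.12, adjusted p = 0.632). Pou5f1 fell below its EpiSC level (-0.65 ± 0.04, 950.1 to 605.9 CPM), and the shared pluripotency core list split, with 6 higher and 7 lower (median -0.02, mean 0.09, camera adjusted p = 0.348, direction down). Primed genes fell in 19 of 21 cases (median -2.01, camera adjusted p = 2.69e-24), with Dnmt3b at -4.48 ± 0.04 and Lef1 at -3.03 ± 0.06. Of the 38 genes in the Hox list 35 rose (median 2.14, camera adjusted p = 0.000211), among them Hoxc13 (4.65 ± 0.16, 0.821 to 20.7 CPM) and Hoxc6 (2.57 ± 0.12, 3.78 to 22.4 CPM), while Hoxb13 fell (-3.30 ± 0.24, chosen after its value was seen). Interferon response and MHC class I genes rose in 15 of 16 cases (median 1.27, camera adjusted p = 0.000634), with Irf7 (3.66 ± 0.13) and B2m (1.52 ± 0.05). All 20 feeder fibroblast markers rose in the same libraries (median 1.51, camera adjusted p = 1.03e-28), led by Lox (3.19 ± 0.04) and Col3a1 (2.51 ± 0.04), and their summed level was 18041 CPM against 5457 in EpiSC and 6272 at day 3. Of genes with at least 10 CPM, Mmrn2 (5.49 ± 0.07) was among the largest rises, and Trh (-8.03 ± 0.07) and Fosb (-6.09 ± 0.10) among the largest falls. In all 12330 genes were called, 6840 higher and 5490 lower, with 2681 and 1780 changed at least 2-fold. With scaling to total counts 45.3% of called genes were higher in place of 55.5%, and the median of all genes moved from 0.08 to -0.07.

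P2 was also compared with day 3 directly, which tests whether the difference from EpiSC changed between the time points. No untreated cells were sampled at these times, so time in culture, passage and feeder share are not separable from treatment. All 14 genes of the shared pluripotency core fell from day 3 to P2 (median -0.72, camera adjusted p = 1.06e-10), including Pou5f1 (-0.91 ± 0.04) and Foxd3 (-1.39 ± 0.05), and so did 21 of 22 naive genes (median -0.65, camera adjusted p = 4.32e-13), with Tbx3 at -1.36 ± 0.04 and Gbx2 at -1.62 ± 0.06. All 23 cell cycle genes fell (median -0.53, camera adjusted p = 3.57e-12), with Mcm5 at -0.84 ± 0.03, and glycolysis genes fell in 17 of 21 cases (median -0.79, camera adjusted p = 6.45e-10). Hox genes rose in 31 of 38 cases (median 1.49, camera adjusted p = 7.53e-06), with Hoxd8 (1.94 ± 0.09, 6.54 to 25.0 CPM) and Meis1 (1.61 ± 0.10). All 12 genes of the mesenchymal list rose (median 1.22, camera adjusted p = 3.84e-11), with Mmp2 (2.07 ± 0.04) and Cdh11 (1.48 ± 0.05), and all 16 interferon and MHC class I genes did (median 1.91, camera adjusted p = 2.87e-15), with Irf7 (3.03 ± 0.10) and H2-K1 (1.90 ± 0.05). The 20 feeder markers rose alongside (median 1.55, camera adjusted p = 5.94e-48), up to Col3a1 (1.94 ± 0.04). The imprinted growth genes H19 (1.99 ± 0.04) and Igf2 (1.88 ± 0.03) led the imprinted list, of which 16 of 25 rose and 6 fell (median 0.41, camera adjusted p = 0.000253). Among genes of at least 10 CPM in either group, Col8a2 (3.30 ± 0.10), Ptx3 (3.26 ± 0.06) and Fmod (3.14 ± 0.11) had the largest rises, and the chloride channel Ano1 (-2.36 ± 0.11), Porcn (-2.20 ± 0.06) and Dnmt3l (-2.06 ± 0.04) were among the largest falls. Some genes of lower level changed more. Of 11501 genes called, 6092 were higher and 5409 lower at P2, with 2189 and 377 changed at least 2-fold, and with RLE size factors 5729 were higher and 5815 lower.

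**Figure D2:**
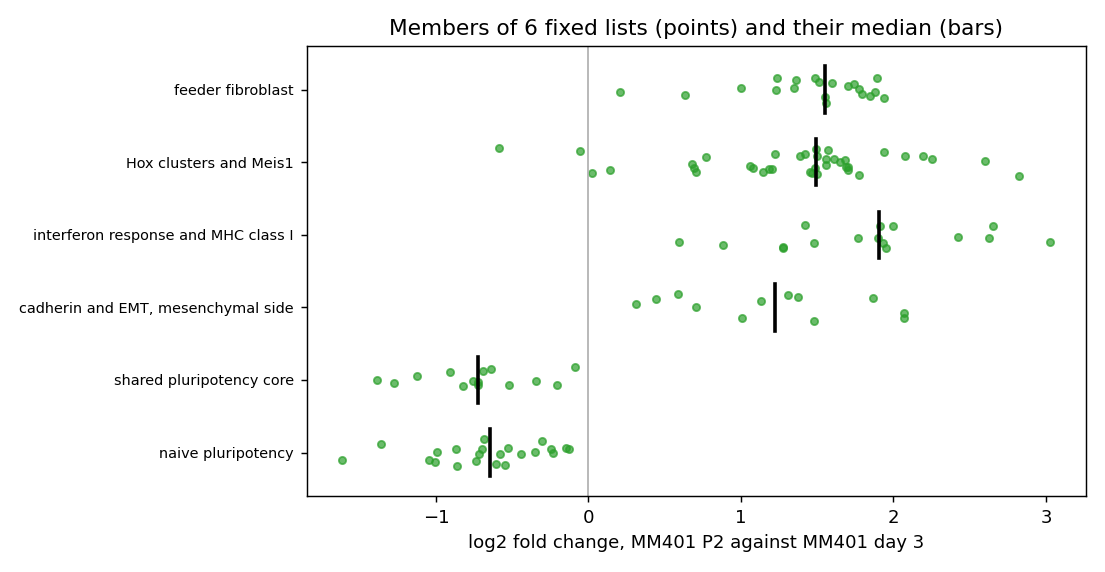
Log2 fold change of P2 against day 3 for each measured gene of 6 lists, 1 point per gene with the list median as a line. Feeder, Hox, interferon and mesenchymal genes lie mostly above 0 (medians 1.55, 1.49, 1.91 and 1.22) and core and naive genes below it (medians -0.72 and -0.65).

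Naive genes in the rES line at passage 30 lay far above their EpiSC level. Naive genes rose in 21 of 22 cases (median 3.17, camera adjusted p = 2.74e-71), including Tbx3 (5.14 ± 0.06, 19.3 to 679 CPM), Tfcp2l1 (4.64 ± 0.05), Nr0b1 (4.05 ± 0.05) and Klf4 (3.57 ± 0.04), and Dppa3 fell (-0.70 ± 0.15). Core genes rose in 12 of 14 cases (median 0.82, camera adjusted p = 0.000126), with Dppa2 (3.78 ± 0.08) and Sox2 (1.68 ± 0.04). Primed genes fell in 18 of 21 cases (median -2.42, camera adjusted p = 1.9e-16), with Grb10 (-4.05 ± 0.05), Dnmt3b (-3.92 ± 0.05) and Sox11 (-4.33 ± 0.08), while Otx2 (1.66 ± 0.06), Etv4 (1.43 ± 0.05) and Sfrp2 (1.30 ± 0.07, chosen after its value was seen) rose. Glycolysis genes rose in 20 of 21 cases (median 1.02, camera adjusted p = 7.21e-17), with the glucose transporter Slc2a3 (1.74 ± 0.03) and Eno2 (3.16 ± 0.06), and germ line genes in 12 of 15 (median 1.65, camera adjusted p = 0.000997), with Mael (4.08 ± 0.15). Neuroectoderm genes fell in 10 of 13 cases (median -1.17, camera adjusted p = 0.00044), with Sox1 (-3.64 ± 0.09) and Nes (-2.79 ± 0.05). Feeder markers fell in 17 of 20 cases (median -1.84, camera adjusted p = 2.21e-21), with Col3a1 at -3.39 ± 0.05. Nrg2 (7.66 ± 0.24), the Wnt antagonist Notum (6.65 ± 0.13) and the MHC class II gene H2-Eb1 (6.21 ± 0.14) had large rises, and Actc1 (-7.82 ± 0.24), Vrtn (-7.18 ± 0.18) and Car2 (-7.15 ± 0.09) large falls. Of 12397 genes called, 6172 were higher and 6225 lower, with 2508 and 2687 changed at least 2-fold. The fall at EpiSC-high genes and the rise at naive genes were also seen at passage 6, where 11983 genes were called, with Tfcp2l1 at 4.33 ± 0.04, Dnmt3b at -4.08 ± 0.05 and a naive list median of 3.10 (camera adjusted p = 6.68e-76).

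Against ESC, rES at passage 30 had higher levels of several naive factors and lower levels of primed, primitive endoderm and stress genes. Klf4 (1.94 ± 0.04, 181 to 695.4 CPM), Prdm14 (1.85 ± 0.05) and Tbx3 (1.33 ± 0.04) were higher, Zfp42 (-1.70 ± 0.04) and Dppa3 (-1.76 ± 0.14) lower. The naive list had 15 genes higher and 5 lower of 22 (median 0.62, camera adjusted p = 5.71e-08). Primed genes were lower in 16 of 21 cases (median -1.34, camera adjusted p = 2.58e-10), with Dnmt3b (-3.16 ± 0.05) and Fgf5 (-4.15 ± 0.22), and 13 of 14 primitive endoderm genes were (median -2.45, camera adjusted p = 1.32e-25), with Lama1 (-3.41 ± 0.04) and Col4a2 (-2.46 ± 0.04), but Gata6 was higher (0.48 ± 0.09, chosen after its value was seen). Stress response genes were lower in 14 of 18 cases (median -1.35, camera adjusted p = 2.69e-12), with Trib3 (-3.03 ± 0.06) and Chac1 (-2.74 ± 0.07). Cholesterol synthesis genes were higher in 19 of 21 cases (median 0.82, camera adjusted p = 6.82e-10), with Nsdhl (1.68 ± 0.05), and cell cycle genes in 21 of 23 (median 0.74, camera adjusted p = 8.48e-11), with Ccnb2 (1.24 ± 0.04). Epithelial genes were lower in 11 of 14 cases (median -0.87, camera adjusted p = 2.36e-09), with Esrp1 (-6.44 ± 0.14) and Grhl2 (-2.71 ± 0.07). Imprinted genes were lower in 19 of 25 cases (median -0.67, camera adjusted p = 1.32e-05), with H19 (-2.48 ± 0.04). The feeder markers were lower too, in 19 of 20 cases (median -1.51, camera adjusted p = 3.69e-32). Across all genes the fold change of rES passage 30 against ESC fell with GC content (Spearman rho -0.2). The list results of this comparison, here and in the next paragraph, were not corrected for that trend.

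Some genes of germ cells and of the cleavage-stage embryo were higher in rES than in ESC. The meiotic gene Stra8 (5.86 ± 0.31), the oocyte homeobox gene Obox6 (5.24 ± 0.17), Pramel7 (4.96 ± 0.19), Dazl (2.73 ± 0.08) and Zscan4d (3.62 ± 0.31, 0.742 to 9.21 CPM) were higher. The list of 2-cell-like genes had 6 higher and 1 lower of 7 with a median of 3.62, but its test did not pass (camera adjusted p = 0.0506), and the germ line list had 8 higher and 5 lower of 15 (median 1.78, camera adjusted p = 0.0178, adjusted p = 0.0587 with an estimated correlation). Lower in rES were the kidney and yolk sac receptor gene Cubn (-6.71 ± 0.22), Cxcl12 (-5.82 ± 0.11) and Gkn2 (at least 218-fold). Of 608 X-linked genes 344 were higher and 125 lower (median 0.54, or 0.55 with genes at 0 counts set at their bound, camera adjusted p = 2.01e-09), and Xist was at 49.1 CPM against 30.9 (0.67 ± 0.12). Tsix, the gene named in the rES genotype, did not differ between them (-0.15 ± 0.35, adjusted p = 0.714, 1.18 and 1.33 CPM), which does not check the label, since the deleted part and the strand are not given. In all 11554 genes were called, 5736 higher and 5818 lower, with 1740 and 2039 changed at least 2-fold. At passage 6, 11252 genes were called against ESC, with Klf4 at 1.85 ± 0.04 and Stra8 at 6.10 ± 0.30, and without MM401 at passage 30 there were 11592, with Klf4 at 1.87 ± 0.04 and Stra8 at 6.17 ± 0.30.

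In passage 30 rES grown without MM401 pluripotency genes changed little, and 8 of 15 genes of the MLL/SET1 methyltransferase complexes were lower than with it. Sox2 (0.04 ± 0.04), Nanog (-0.05 ± 0.04), Klf4 (-0.07 ± 0.04), Otx2 (-0.07 ± 0.05) and Dnmt3b (-0.08 ± 0.06) were not called (adjusted p 0.523, 0.39, 0.243, 0.368 and 0.396). Smaller changes were called for Pou5f1 (0.15 ± 0.04), Esrrb (-0.14 ± 0.03), Tbx3 (-0.17 ± 0.04) and Zfp42 (0.31 ± 0.05). Leaving out 1 library changed some of these calls. Pou5f1 lost its call without rES passage 30 replicate 2 (0.11) or replicate 2 without MM401 (0.08), and Tbx3 without rES passage 30 replicate 1 (-0.10) or replicate 2 without MM401 (-0.14). Klf4 gained a call without rES passage 30 replicate 2 (-0.13), and Nanog (-0.12) and Wdr5 (0.12) did without replicate 1 of the cells grown without MM401. The naive list had 5 genes higher and 8 lower (median -0.06, camera adjusted p = 0.931), and the Hox list did not move on balance (median 0.05, camera adjusted p = 0.607). Of 15 MLL/SET1 subunit genes 8 fell (median -0.15, camera adjusted p = 3.45e-09; 9 adjusted over the list alone), including Setd1b (-0.66 ± 0.05, 102 to 64.3 CPM), Kmt2a (-0.55 ± 0.05, 165.4 to 112.8 CPM), Kmt2c (-0.50 ± 0.04) and Kmt2d (-0.48 ± 0.04), while Wdr5 was not called (0.08 ± 0.03, adjusted p = 0.0816). Over all genes the fold change of this comparison fell with transcript length (Spearman rho -0.38, against -0.15 to 0.15 in the other comparisons). With that trend removed 2504 genes were called in place of 3200. The MLL/SET1 genes have long transcripts, and 7 of the 8 stayed called. The median of the 8 moved from -0.43 to -0.23 and that of all 15 from -0.15 to -0.08 (camera adjusted p = 5.96e-05). Cytochrome c oxidase genes rose in 8 of 14 cases (median 0.23, camera adjusted p = 2.44e-07, adjusted p = 0.0666 with an estimated correlation), with Cox7a2 (0.40 ± 0.04), but they have short transcripts, and with the length trend removed 4 rose (median 0.09, camera adjusted p = 0.048). FGF and ERK targets fell in 7 of 16 cases (median -0.12, camera adjusted p = 0.000424, adjusted p = 0.0666 with an estimated correlation), with Egr1 (-0.55 ± 0.05), Spry4 (-0.38 ± 0.05) and Myc (-0.47 ± 0.06). Among genes of at least 10 CPM in either group, the neurotrophic factor gene Nrtn (1.42 ± 0.12), Scand1 (1.37 ± 0.22) and Tcf15 (0.75 ± 0.07) were among the 10 largest rises, and Chac1 (-0.82 ± 0.09), Lef1 (-0.76 ± 0.10) and the RNA polymerase gene Polr2a (-0.64 ± 0.05) among the 10 largest falls. Scand1 lost its call with the 4 compared libraries alone (adjusted p = 0.102, with 9.9e-53 to 0.102 over its alternatives), and the genes that changed 2-fold were mostly of lower level. Of 3200 genes called, 1689 were higher and 1511 lower, and 17 and 27 changed at least 2-fold. A fit of the 4 compared libraries alone, which takes its spread from them only, called 2627 genes. The balance turned with RLE size factors (1443 higher, 1705 lower) and with DESeq2 (1345 and 1568). The count was 1991 without replicate 2 of the cells grown without MM401, and 1 rES passage 30 library held more of the ribosomal RNA precursor Rn45s than the other (2.005% and 0.548% of counts).

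Between passage 6 and passage 30 feeder-type transcripts of the rES line fell, while core pluripotency genes moved little. All 20 feeder markers fell (median -1.04, camera adjusted p = 1.24e-120), from a summed 3593 to 1712 CPM, with Acta2 (-1.39 ± 0.04) and Lox (-1.10 ± 0.04). Mesenchymal genes fell in 11 of 12 cases (median -0.65, camera adjusted p = 5.95e-16), with Vim (-1.04 ± 0.03), Hox genes in 16 of 38 (median -0.67, camera adjusted p = 0.00609, adjusted p = 0.0701 with an estimated correlation), with Hoxc6 (-1.18 ± 0.17), and interferon genes in 11 of 16 (median -0.63, camera adjusted p = 8.76e-05), with H2-D1 (-0.74 ± 0.06). Core genes rose in 7 of 14 cases by small steps (median 0.13, camera adjusted p = 0.00283), with Pou5f1 at 0.17 ± 0.04, and Tfcp2l1 rose by 0.31 ± 0.04. Fosb (-2.21 ± 0.17) and Siglecg (-1.91 ± 0.16) fell most among genes of at least 10 CPM in either group. Of 4167 genes called 1828 were higher and 2339 lower, with 18 and 392 changed at least 2-fold, and the count was 2711 without passage 6 replicate 1 and 2757 without passage 6 replicate 2. The share of called genes that were higher was 43.9%, 54.3% with the RLE size factors and 33.3% with total counts. Fold changes between passages fell with GC content (Spearman rho -0.22), and the list results were not corrected for this.

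**Figure D3:**
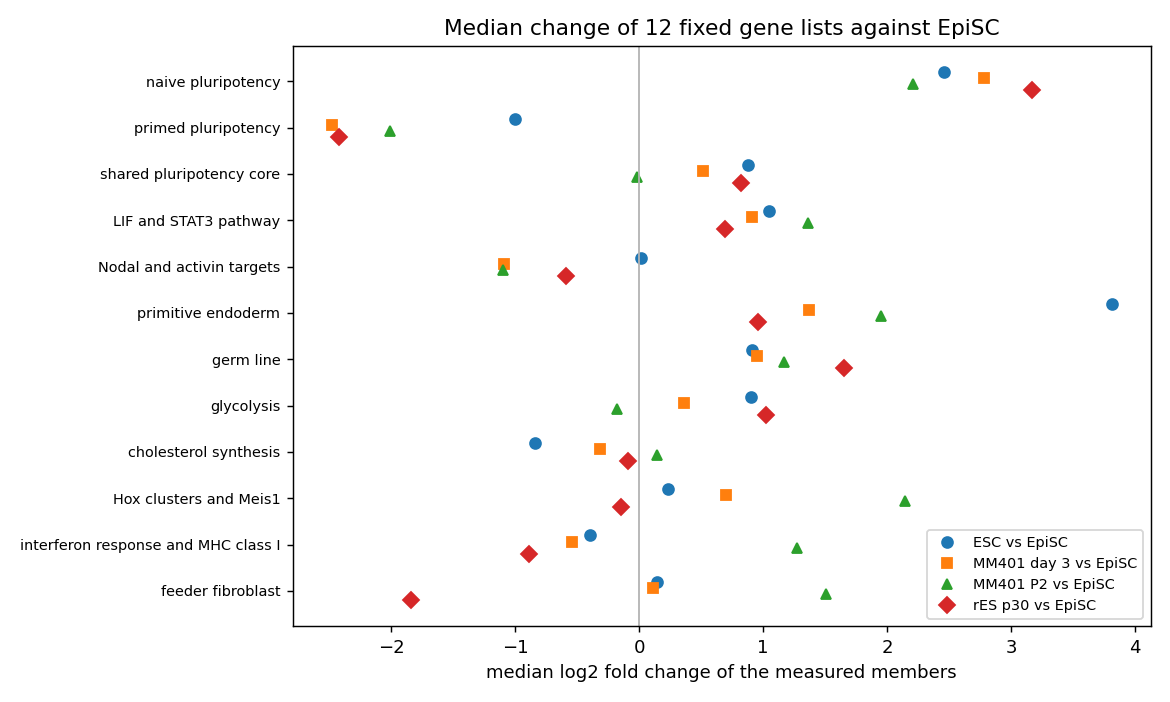
Median log2 fold change against EpiSC of 12 gene lists in ESC, MM401 day 3, MM401 P2 and rES passage 30. The naive list lies between 2.21 and 3.17 in all 4, and the feeder list is highest at P2 (1.51) and lowest in rES (-1.84).

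On a scale between the 2 reference states each treated or reverted group lay between EpiSC and ESC on average, while many single genes lay outside them. The scale was set from 0 (EpiSC mean) to 1 (ESC mean) over the 4523 genes called between them with at least a 2-fold change, and each library was placed on it by a least-squares slope. Day 3 lay at 0.712 (SD 0.0007 over 2 libraries), P2 at 0.619 (SD 0.0025), rES passage 6 at 0.737 (SD 0.0017), passage 30 at 0.758 (SD 0.0026) and passage 30 without MM401 at 0.758 (SD 0.0039). The difference between day 3 and P2 was larger than the spread between replicates. The EpiSC mean enters both sides of each slope, so any difference particular to the 2 EpiSC libraries moves every group towards 1. A value above 0 alone therefore does not show that a group resembles ESC. In rES passage 30, 35.3% of the genes higher in ESC and 38.4% of those higher in EpiSC lay beyond their ESC level, and 16.6% and 10.1% moved the opposite way. The first principal component of all genes (45.4% of the variance) placed rES libraries (-72.4 to -51.7) and day 3 libraries (13.3 and 13.0) beyond ESC (28.6 and 28.9) as seen from EpiSC (97.8 and 98.2), and P2 libraries (54.7 and 54.5) between them. Among single genes, Klf4 stood at 331.9 CPM at day 3 and 695.4 CPM in rES passage 30 against 181 CPM in ESC, and Dnmt3b at 61.9 and 37.4 CPM against 335.2 CPM.

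**Figure D4:**
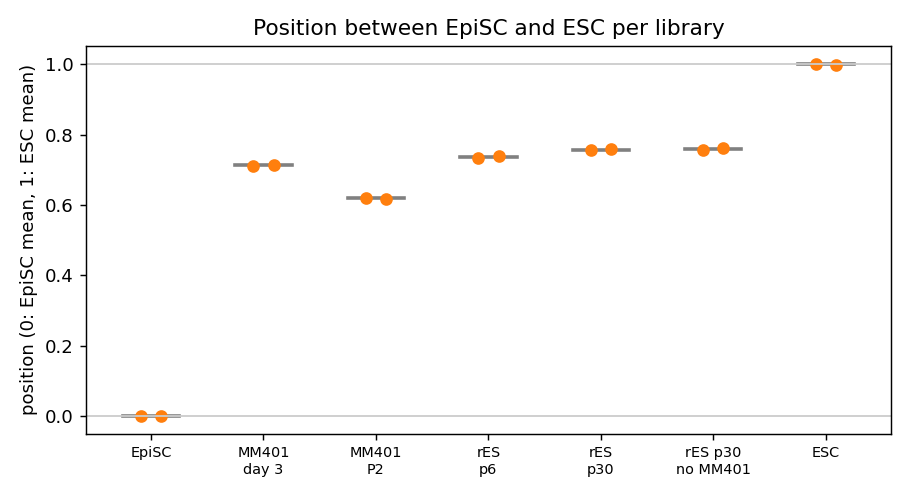
Place of each library on the scale from the EpiSC mean (0) to the ESC mean (1), over 4523 genes. The 2 libraries of each group nearly coincide, with P2 at 0.619 and rES passage 30 at 0.758.

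Many genes were called in the same direction as in ESC against EpiSC: 8209 at day 3, 7513 at P2, 8060 in rES passage 6, 8023 in passage 30 and 7929 without MM401, with 1762, 2234, 1558, 1836 and 1957 in opposite directions. Tfcp2l1, Zfp42 and Tbx3 were among the shared rises, and Sox11, Grb10 and Lefty1 among the shared falls. Independent lists of these sizes would share 4634, 4590, 4462, 4618 and 4630 genes. Simulations without an effect yield few calls by construction, so the at most 1 gene shared in 20 of them sets no scale for these numbers. The correlation of the fold changes over genes was 0.70, 0.63, 0.67, 0.65 and 0.64, against 0.58, 0.56, 0.45, 0.46 and 0.46 in the simulations. The covariance of the fold changes over genes was 1.311, 1.122, 1.338, 1.38 and 1.395, against 0.059 to 0.06 in the simulations. Both sides of each overlap use the same 2 EpiSC libraries, which were not split because each side would keep a single library, so part of the overlap may come from these shared controls.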

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

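The tests of feeder RNA and library depth below were chosen after the results were seen. A difference between groups marked 3 results of the P2 and day 3 comparison. Against EpiSC, 1473 genes were called in opposite directions at day 3 and P2 with a called difference, 578 up then down and 895 down then up, of which 28 changed at least 2-fold each way. Pou5f1 rose at day 3 (0.26 ± 0.04) and fell at P2 (-0.65 ± 0.04), a difference of -0.91 ± 0.04. Otx2 rose at day 3 (0.79 ± 0.05) and fell at P2 (-0.35 ± 0.06), a difference of -1.14 ± 0.05.

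More feeder fibroblast RNA at P2 could raise Hox, mesenchymal and interferon genes and dilute pluripotency genes. If so, few members would rise by more than the feeder marker with the largest rise, Col3a1 (1.94 ± 0.04). Above it by over 2 standard errors lay 2 Hox genes (Hoxa2 and Hoxa9) and 1 mesenchymal gene (Mmp2). More feeder fibroblast RNA thus stays open for both lists in the step from day 3 to P2. Also above it lay 4 interferon genes (Ifit1, Ifit3, Irf7 and Oasl2). Col3a1 sets no upper limit, since a marker also made by other cells rises by less than the feeder share. Genes outside the lists, such as Col8a2, Ptx3 and Fmod, also rose by more than Col3a1. The 4 genes therefore do not decide whether feeder RNA raised the interferon list. Against EpiSC the Hox median was 2.14 at P2 and 0.70 at day 3, beside feeder medians of 1.51 and 0.11. Feeder RNA was not tested as a cause of those Hox changes, which exceeded the feeder medians. All 31 Hox genes called higher stayed so after thinning to the shallowest library, so these calls did not depend on the number of reads. Thinning leaves the expected fold changes as they are, so it cannot address other differences that go with the deeper libraries. Feeder RNA may also differ in state between cultures, which was not tested, and the cause stays open.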

How the results depend on the processing

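Counts of genes called stayed within 1.5 times their value in all 11 comparisons with DESeq2, RLE size factors, total counts, no filter, the 4 compared libraries alone or a replicate block (for example 12048 in ESC against EpiSC and 3180 on withdrawal of MM401). They also did with the alternatives added after seeing the data, namely thinning to the shallowest library, leaving out Rn45s and leaving out the 751 genes that follow the feeder markers. Asking also for a 2-fold change gave 4523 (ESC), 4450 (day 3), 4461 (P2), 5195 (rES passage 30) and 4657 genes (passage 6) against EpiSC, 3779 (passage 30), 3361 (passage 6) and 3908 (without MM401) against ESC, 44 on withdrawal, 2566 for P2 against day 3 and 410 between passages, by its own construction.

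With each library of the compared groups left out in turn, the counts ranged from 11131 to 11254 (ESC), 11365 to 12150 (day 3), 11237 to 12009 (P2), 11497 to 11717 (rES passage 30) and 11015 to 11150 (passage 6) against EpiSC. They ranged from 10511 to 10733 (passage 30), 10040 to 10262 (passage 6) and 10626 to 10833 (without MM401) against ESC, 10936 to 11048 for P2 against day 3, 1991 to 2751 on withdrawal and 2711 to 3619 between passages. Without rES passage 30 replicate 2, which is outside the compared groups and was left out as an alternative added after seeing the data, the counts were 12210 (ESC), 12584 (day 3), 12460 (P2) and 12091 (passage 6) against EpiSC, and 11356 (passage 6) and 11709 (without MM401) against ESC. With a library of the group, EpiSC or ESC left out, positions ranged from 0.694 to 0.715 (day 3), 0.606 to 0.626 (P2), 0.714 to 0.738 (rES passage 6) and 0.737 to 0.759 (passage 30 and without MM401). Shared calls ranged from 7385 to 8099, 6690 to 7402, 7328 to 7613, 7270 to 7774 and 7215 to 7624 in the order day 3, P2, passage 6, passage 30 and without MM401, and were 2586, 2312, 2665, 2721 and 2712 at 2-fold.

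Over all genes tested the positions were 0.699 (day 3), 0.601 (P2), 0.722 (passage 6), 0.745 (passage 30) and 0.745 (without MM401). With a prior count of 0.5 they were 0.712 (day 3), 0.731 (passage 6) and 0.751 (passage 30), with RLE 0.735 (passage 6), and without feeder-following genes 0.715 (day 3). The order of the groups held where all were recomputed, and the cause of the shifts was not tested.

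Of 319 list tests 156 passed, 154 to 161 with a library left out, and 95 with an estimated correlation (the cause was not tested). The list of primitive endoderm genes between rES passages reversed without feeder-following genes (adjusted p = 0.851). Uncalled genes changed sign: Dppa3 at P2 (-0.08 with total counts, -0.05 to 0.20 with a library left out, lowest without EpiSC replicate 2), Tsix in rES passage 30 against ESC (-0.78 to 0.25, highest without rES passage 30 replicate 2), and on withdrawal Sox2 (-0.03 to 0.12, lowest without rES passage 30 replicate 2, -0.01 without replicate 1 of cells grown without MM401), Nanog (-0.12 to 0.01, highest without replicate 2 of those cells) and Klf4 (-0.13 to 0.00, highest without rES passage 30 replicate 1). The cause was not tested. Cdh1 at day 3, not called, was called lower with total counts (-0.22). Scand1 lost its call on withdrawal with the 4 compared libraries alone (1.37, adjusted p = 0.102, with 9.9e-53 to 0.102 over its alternatives).

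Replicate numbers pair no libraries, as the correlation of replicate differences over 21 pairs of groups ran from -0.03 to 0.04 (median 0). Depth bears on comparisons of the deeper MM401 libraries, where thinning gave 10238 genes in place of 11501 for P2 against day 3 and 11922 in place of 12443 for day 3 against EpiSC.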

Other observations

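Of the tests below, rES passage 30 replicate 2 alone, the matched random lists and both dose tests of chromosome 11 were chosen after the results were seen. The other tests also address patterns first seen in these data. The choice of chromosome 11 and the setting aside of chromosome 3 rest on their medians in these data.

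MLL/SET1 subunit genes were lower in rES grown without MM401. The 8 genes called lower had a median of -0.43, and all 8 stayed called with the trend over GC content removed. With the trend over transcript length removed 7 stayed called, the median moved to -0.23, and Kdm6a moved from -0.15 ± 0.05 to -0.08 ± 0.04 (adjusted p 0.0148 to 0.239), as its fold shrank. With rES passage 30 replicate 2 left out 7 stayed called, and among 10000 random lists matched for length and level 1.76% had a median as low as that of the 15 members (-0.15). For the 8 single genes, between 1% (Kmt2a and Setd1b) and 28% (Kdm6a) of matched genes were lower. Transcript length may therefore account for part of the size of the change. Whether it accounts for all of it is not decided by the random lists, because this list was singled out from these same data. A response of these genes to withdrawal of the inhibitor is a hypothesis that was not tested further. Kmt2a was also lower at day 3, with MM401 added (103.1 CPM, against 147.8 CPM in EpiSC). The median of the 15 members was 0.24 in that comparison.

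Genes of chromosome 11 were higher in EpiSC than in ESC. Relative to all autosomes their median log2 fold change in ESC was -0.319, against -0.072 to 0.136 for the autosomes other than 3 and 11 and -0.255 for chromosome 3, and it was -0.348 with the trends over GC content and transcript length removed. Of 5 stretches along the chromosome 4 lay under the lowest other autosome, so the difference was not limited to a single short stretch. Stretch 1 did not (-0.023, bootstrap interval -0.102 to 0.102), and its interval leaves out the chromosome's median. How far stretches of this size vary on other autosomes was not measured, so stretch 1 does not decide whether the dose of the whole chromosome was larger. In 6 of 6 groups the chromosome 11 median lay under the lowest other autosome, and chromosome 3 did so too (-0.255 to -0.144). Day 3 and P2 cells came from EpiSC, yet their chromosome 11 medians against EpiSC were -0.306 and -0.314, near the -0.319 of ESC. A larger dose in the EpiSC culture that was treated would be passed on to them, so these values argue against it. Whether the sequenced EpiSC were that same culture is not given in the sources used here. A larger dose in the sequenced EpiSC alone, over part or all of chromosome 11, stays open. All 6 groups share the same 2 EpiSC libraries, no DNA was analysed here, and the cause stays open.

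X-linked genes had a median relative to the autosomes of 0.527 in rES passage 6, 0.607 in passage 30 and 0.563 without MM401, against -0.188 in ESC, -0.225 at day 3 and -0.077 at P2, each against EpiSC. The genotype label of the rES lines names Tsix, which lies on this chromosome, and genotype and line were not separable from state.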
